A study of Bos taurus with 8 samples.

How the data were processed

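The series holds 8 arrays, 1 per heifer, of DNA from the arcuate nucleus of the hypothalamus. Per the labels, the feeding schedules began at 4.5 months of age and ended at 8.5 months, when tissue was taken, with a target gain of 1 kg per day (high-gain, heifers 1 to 4) or 0.5 kg per day (low-gain, heifers 5 to 8). DNA rich in methylated CpG sites was captured with a methyl-CpG binding domain protein, which holds double-stranded DNA carrying methylated CpG. Per the labels, 3 µg each of captured (enriched) and total (input) DNA were labelled with Alexa Fluor 647 and Alexa Fluor 555 and hybridised together, so each array gave its own enriched-to-input ratio. No dye was swapped, so a dye effect common to all arrays stays in every ratio but cancels between groups.

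Per the file headers, spots were read with Agilent Feature Extraction 10.7.1.1 (protocol ChIP_107_Sep09), and the deposited intensity values used here are its processed signals, background-subtracted, detrended and linearly dye-normalised. The authors' table of processed values held a log2 ratio per probe that equalled the log2 ratio of background-subtracted median signals within a tolerance of 0.0001 at every spot where both differences were positive. It was neither centred nor dye-normalised, and its array medians were -0.42, 0, -0.51, -1.07, -0.87, -0.89, -1.52 and -1.82 for heifers 1 to 8. The deposited log10 ratio of the scanner software was not used. Probe positions are given as in the files, on Btau_3.1 per the file headers. The gene table at hand was on another assembly and the files pair no probe with a gene, so the test per gene and the 15 gene lists, cell type markers among them, were not run. Items are therefore named by position, and whether they lie in a gene, exon or intron was not analysed here.

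From these values log2(enriched/input) was computed for 10249 non-control probes, 28 spots with an outlier flag were left out, and each array was centred on its median. A value of 0 is thus the median probe of that array, not an absence of methylation, and a change shared by all probes is removed. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). This was done per probe, per region (at least 3 probes with starts at most 1000 bp apart; 960 regions) and, as an addition made after seeing the data, per tiled locus (at least 10 probes, gaps of at most 20000 bp; 97 loci). Runs were at least 3 neighbouring probes within 1000 bp, each at unadjusted p under 0.05 with the same sign. The enrichment profile tested the mean of both group means against 0 per region, and called regions at an absolute mean of at least 1 on the log2 scale. Single values per array were compared with exact permutation tests, two-sided, for which 4 against 4 allows no p below 0.0286.

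These designs, the main alternatives and the rule for naming were fixed before the data were examined. The rule took up to 12 regions or probes per direction past the threshold whose groups did not overlap, then, since that gave fewer than 20, up to 12 runs per direction by the sum of absolute moderated t, and the 5 regions highest and the 5 lowest in the enrichment profile. Where a probe was not well above background in the enriched channel on any array of 1 group, a bound was computed: the dim group took, per array, the higher of its own signal and the lowest signal among probes well above background. Alternatives covered background correction, loess, scaling and quantile normalisation, filters on dim probes, the authors' values, the enriched channel alone, array weights, a robust trended fit, slide position, each heifer left out, thresholds and gaps. Normexp (offset 50) was planned on mean signals, which the files do not hold, and was run on medians instead, as an addition made after seeing the data. All 8 arrays shared 1 slide and 1 scan date, so of what was recorded only the position on the slide could serve as a batch. The labels give no batch of capture or labelling, so such a batch could not be tested.

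The steps were tested on data simulated from the spread of each probe over these arrays, with noise drawn independently for each probe and array. Of 200 probes shifted between the groups among 10249, 0.5% were recovered at a log2 shift of 2, 51.5% at 3 and 75.5% at 4. Of 100 regions shifted among 960, 60% were recovered at a log2 shift of 1 and 97% at 2. Runs touched 20 of 100 shifted regions at a shift of 1 and 83 at 2, and 1 run arose with no shift at all. In the real arrays, neighbouring probes with starts at most 200 bp apart correlated at 0.101 to 0.313 within an array. That correlation includes the mean profile of the probes, which the simulation kept, so it does not measure shared noise. If neighbouring probes share noise, recovery of regions and runs may be lower than simulated, and runs without a shift more frequent. The precision is limited by the number of arrays. The input channel was well above background at 79.6% to 93.2% of probes per array and the enriched channel at 49.6% to 76.1%.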

Results

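DNA methylation in the arcuate nucleus was compared between heifers on a high-gain and a low-gain feeding schedule, to ask whether nutrition before puberty alters methylation in this feeding and reproductive centre of the hypothalamus. Each of the 4 high-gain and 4 low-gain heifers gave 1 array. The 10249 probes lay in tiled stretches of 29 chromosomes, with the most on chromosome 29 (1698 probes between 49860608 and 51627535), chromosome 21 (892 probes) and chromosome 5 (890 probes). The median distance between neighbouring probe starts was 395 bp. Values are log2 ratios of methyl-CpG-enriched to input DNA relative to the median probe of each array.

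At 1 region, on chromosome 29 from 50882389 to 50883681, enrichment was higher in high-gain heifers. Its log2 ratio was 0.64 ± 0.18 (SD, n = 4) in high-gain and -1.48 ± 0.77 (SD, n = 4) in low-gain heifers. The difference was 2.12 with a standard error of 0.34 (limma, Benjamini-Hochberg adjusted p = 0.0308 over 960 regions), and every high-gain array lay above every low-gain array. The rule for naming required that separation, so it is no added support. This region was picked from 960 by its difference, whose size therefore tends to be overstated. Of its 3 probes, those starting at 50882389 and 50882814 differed by 3.70 and 2.54, and the one starting at 50883621 differed by 0.14. That last probe was not well above background in the enriched channel on any low-gain array, and was so on only 2 high-gain arrays. With its dim low-gain signals raised to the bound, these processed signals gave a region 3.51-fold higher in high-gain. That is not a lower limit over other settings. Low-gain heifer 5 lay at -0.35, and low-gain heifers 6, 7 and 8 at -1.91, -1.63 and -2.04. The input channel of this region differed by -0.27 (standard error 0.20).

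The call on this chromosome 29 region was lost without high-gain heifers 1, 2, 3 or 4 (limma, adjusted p = 0.113, 0.0933, 0.0637 and 0.0743) and without low-gain heifers 6, 7 or 8 (0.168, 0.157 and 0.135). The differences were then 2.05, 2.17, 2.11 and 2.17, and 1.98, 2.08 and 1.94. The call held without low-gain heifer 5 (limma, adjusted p = 0.000274), and over all alternatives the adjusted p ranged from 0.000203 to 0.331. The difference was 1.82 within slide row 1 and 2.43 within slide row 2, each with 2 heifers per group, and 2.12 with the row as a block (adjusted p = 0.0476). With the slide column as a block it was 2.27 and did not pass (limma, adjusted p = 0.331), where only the columns of heifers 2 and 7 and of heifers 4 and 6 held both groups. Without the brightest input probes it was 1.34 and did not pass either (limma, adjusted p = 0.120), the dim probe being 1 of the 2 left. The call was also lost with loess (1.52, limma, adjusted p = 0.180), with the enriched channel alone (1.85, 0.154) and over probes well above background in input (3.12, 0.0701) or in both channels (3.12, 0.137).

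No other region passed, the next smallest adjusted p being 0.111 (limma). At unadjusted p under 0.05, 60 regions were higher and 79 lower in high-gain heifers, where 48 would be expected from 960 tests. Together they numbered 279 without low-gain heifer 5, 89 without high-gain heifer 2, 85 without low-gain heifer 7 and 76 without low-gain heifer 8. The lower ones gathered on chromosome 29, with 35 of its 231 regions lower and 9 higher. Its lower regions numbered 74 without low-gain heifer 5, 15 without high-gain heifer 2, 22 without high-gain heifer 1 or low-gain heifer 6, 17 without low-gain heifer 7 and 18 without low-gain heifer 8, and 10 within slide row 1 and 24 within slide row 2. Its higher regions numbered 15 without high-gain heifer 3 or low-gain heifer 5 and 5 without low-gain heifer 8. The direction on chromosome 29 turned with normexp background correction (25 higher, 11 lower). Over probes well above background in input 12 were higher and 20 lower, and in both channels 5 and 13. With loess 7 were higher and 39 lower, and with array weights 21 and 84. Chromosome 6 had 6 of 32 regions higher and 0 lower, and chromosome 22 had 0 of 16 higher and 4 lower. None of the 97 tiled loci passed (limma, smallest adjusted p = 0.240), with 4 higher and 10 lower at unadjusted p under 0.05 against 4.85 expected. Without low-gain heifer 5, 10 loci passed, and without high-gain heifer 4, 2 did (limma). Those at unadjusted p under 0.05 numbered 33 without high-gain heifer 4, 23 without low-gain heifer 5, 9 without high-gain heifer 2 or low-gain heifer 6, 7 without high-gain heifer 1 or low-gain heifer 7 and 6 without low-gain heifer 8.

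None of the 10249 probes passed either (limma, smallest adjusted p = 0.119). At unadjusted p under 0.05, 739 probes were higher and 536 lower in high-gain heifers, against 512.45 expected in all. The groups did not overlap at 702 of the 10222 probes with a value on all arrays, or 6.87%, where the mean over all 35 splits into 4 and 4 is 2.86%. Single splits can lie far from that mean, since probes share the same arrays. The share was not counted in the other splits, so it does not show an excess due to the feeding groups. In the input channel 512 probes reached unadjusted p under 0.05 and 0 passed (limma). Without low-gain heifer 5, 308 probes and 25 regions passed (limma), and 2342 probes reached unadjusted p under 0.05. Without any other single heifer 0 probes and 0 regions did (limma, 745 probes, without low-gain heifer 8, to 1405 probes and 76 to 182 regions at unadjusted p under 0.05). With the slide row as a block 0 probes passed (limma, 1327 at unadjusted p under 0.05), and within slide rows 1 and 2 also 0 (641 and 1240). With array weights many probes and regions did pass (limma), with counts in the section on processing.

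Neighbouring probes that differed together formed 13 runs, 9 higher and 4 lower in high-gain heifers, holding 42 probes. These runs are described by values, and their probes did not pass the adjusted threshold. They were picked by these same differences, so the sizes below tend to be overstated. The groups did not overlap in 9 of the 13 runs, which such picking favours. The number of runs was 30 without low-gain heifer 5, 6 without high-gain heifer 2, low-gain heifer 6 or low-gain heifer 7, 7 without low-gain heifer 8 and 8 without high-gain heifer 1. It was 13 with the slide row as a block, 4 within slide row 1 and 12 within slide row 2. On chromosome 21, 3 of the higher runs lay within 1 tiled locus (65721186 to 65899733). Their differences, high-gain minus low-gain, were 2.69 at 65831805 to 65832423, 2.35 at 65871171 to 65871698 and 2.53 at 65897495 to 65898115, with standard errors of 0.57, 0.50 and 0.60. At the middle one the high-gain arrays averaged 0.33 ± 0.30 (SD, n = 4) and the low-gain arrays -2.02 ± 0.53 (SD, n = 4), with low-gain heifer 5 at -1.97. There 1 of the 3 probes was not well above background in the enriched channel on any low-gain array, and the difference was 1.11 with normexp background correction, so no fold is given. The run at 65831805 differed by 1.34 within slide row 1 and 4.05 within slide row 2, and by 1.72 with loess, which gave 1.63 at 65897495. At the last one low-gain heifer 5 lay at 0.33, near the high-gain mean of 0.65 ± 0.14 (SD, n = 4). The remaining run on chromosome 21, at 6612227 to 6612846, differed by 2.22 (standard error 0.53).

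Among the other higher runs, the one with the largest sum of absolute moderated t (12.7) held 4 probes on chromosome 10 at 29527570 to 29528405. It averaged 0.41 ± 0.43 (SD, n = 4) in high-gain and -2.03 ± 1.48 (SD, n = 4) in low-gain heifers, with low-gain heifer 5 at 0.15, inside the high-gain range. The 4-probe run on chromosome 2 at 54458522 to 54459402 differed by 2.26 (standard error 0.57), with the groups touching at -0.99 in low-gain heifer 5. The run on chromosome 7 at 53980015 to 53980709 differed by 2.03 (standard error 0.51), with no overlap and low-gain heifer 5 at -2.27. The runs on chromosome 5 at 51895471 to 51896901 and chromosome 19 at 43790345 to 43791057 differed by 1.89 (standard error 0.54) and 1.73 (standard error 0.54), the former with high-gain heifer 4 at 1.66, above the other high-gain heifers (0.45 to 0.58). In the chromosome 19 run low-gain heifer 5 lay at -0.13, inside the high-gain range. With loess the differences on chromosomes 2, 7 and 19 were 1.31, 1.24 and 1.02.

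Of the runs lower in high-gain heifers, the one on chromosome 11 at 13515582 to 13517135 had all low-gain arrays between 1.14 and 1.95 and all high-gain arrays at or under 0.32. It differed by -1.85 (standard error 0.50). The runs on chromosome 28 at 45979971 to 45981834 and chromosome 16 at 48292424 to 48293478 differed by -1.72 (standard error 0.52) and -1.24 (standard error 0.50). In the chromosome 28 run low-gain heifer 5 lay at 0.45, inside the high-gain range, which reached 0.51. With normexp background correction the differences on chromosomes 11 and 28 were -0.68 and -0.70. The chromosome 16 run differed by -0.26 with normexp (unadjusted limma p = 0.198), by -0.75 with the authors' values centred (0.142) and by -0.89 over probes well above background in input (0.0707) or in both channels (0.0823). Its p was 0.178 with the slide column as a block and 0.107 within slide row 2. It had an unadjusted limma p of 0.0564 without high-gain heifer 1, 0.0747 without high-gain heifer 2 and 0.0511 without low-gain heifer 8. In each of these 3 runs, 1 of the 3 probes was not well above background in the enriched channel on any array, and in the chromosome 16 run 2 of the 3 were not on any low-gain array. The 4-probe run on chromosome 17 at 60099960 to 60100797 differed by -1.70 (standard error 0.53), but the difference lay in the input channel (1.82), with 0.11 in the enriched channel. It was -0.51 with normexp, -0.60 with loess (unadjusted limma p = 0.172) and -0.80 with the authors' values centred (0.140). No low-gain array had an enriched signal well above background at any of these 4 probes, so no fold is given. Within slide row 1 alone, of the 13 runs those on chromosomes 2 and 7 and on chromosome 21 at 65871171 kept an unadjusted limma p under 0.05.

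**Figure D1:**
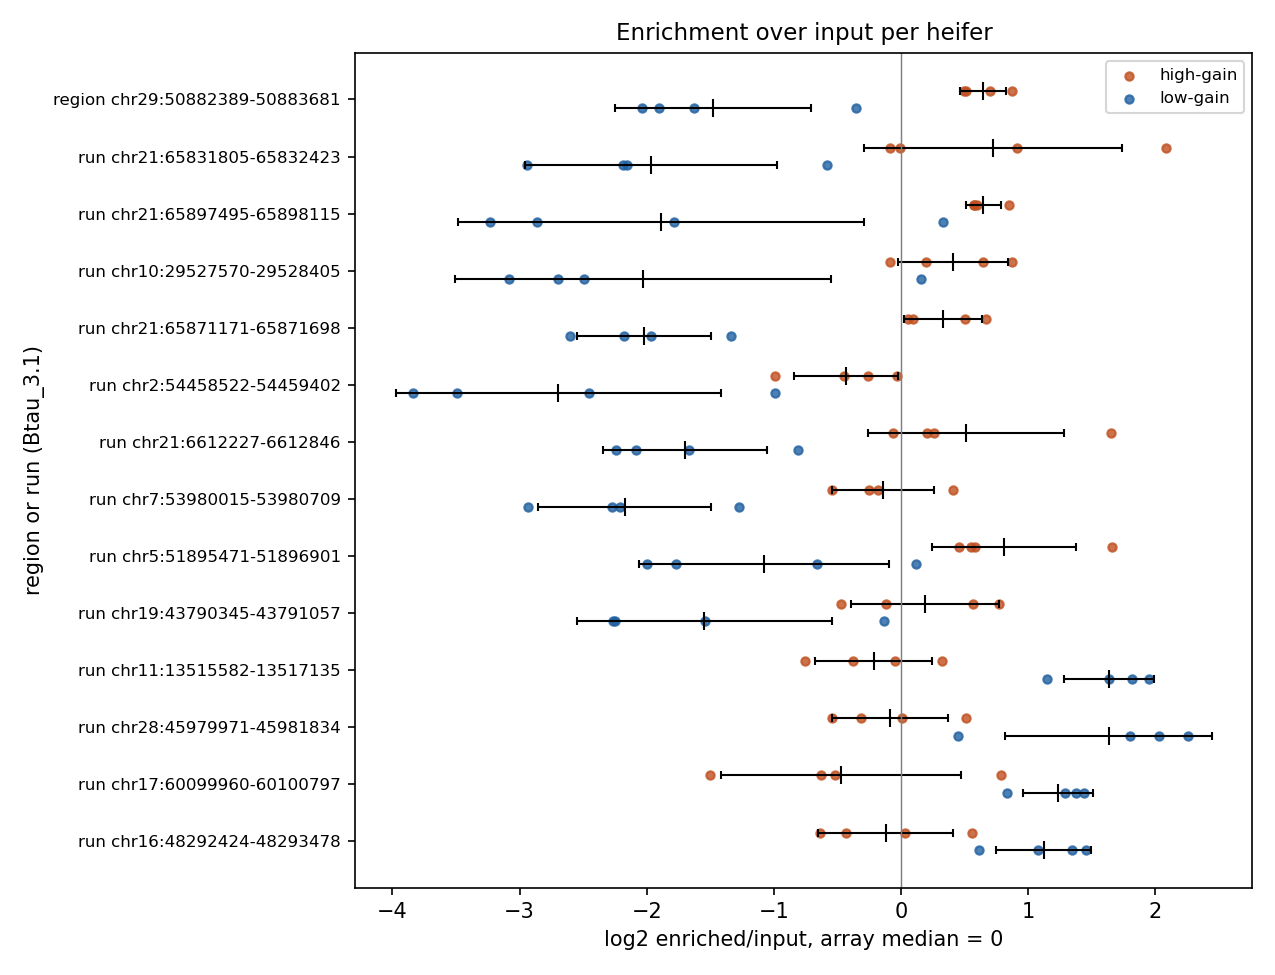
Log2 enriched-to-input ratio (x axis, array median at 0) of the chromosome 29 region and the 13 runs (y axis, Btau_3.1 positions), with a point per heifer, ticks for group means and bars for SD (n = 4 per group). In the chromosome 29 region the high-gain heifers lie between 0.49 and 0.87, while low-gain heifer 5 lies at -0.35, apart from the other low-gain heifers.

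In the mean of both group means, 10 of 960 regions lay at least 1 log2 unit under the array median and 0 lay as far above it, while 124 differed from it at adjusted p under 0.05 (limma). The lowest was on chromosome 7 at 42479459 to 42481495, with a mean of -1.45 (standard error 0.18, n = 8; limma, adjusted p = 0.000879) and below 0 on 8 of 8 arrays. Next came chromosome 29 at 50600406 to 50601862 (-1.39), chromosome 20 at 34007696 to 34010156 (-1.37), chromosome 8 at 115267100 to 115267861 (-1.36) and chromosome 6 at 36522813 to 36524177 (-1.17). The value and place of the chromosome 8 region rest in part on 1 of its 3 probes that was not well above background in the enriched channel on any low-gain array. The highest were chromosome 19 at 38749277 to 38750244 (0.77), chromosome 29 at 51301146 to 51302187 (0.75), chromosome 29 at 50373046 to 50374518 (0.71), chromosome 11 at 3368339 to 3369975 (0.69) and chromosome 5 at 51734288 to 51735067 (0.69), the last not past the threshold (limma, adjusted p = 0.118). Some of these means joined unlike group values that did not pass the adjusted threshold. The chromosome 20 region was at -0.79 ± 0.55 (SD, n = 4) in high-gain and -1.95 ± 0.93 (SD, n = 4) in low-gain heifers, and the chromosome 19 region at 0.30 ± 0.11 and 1.23 ± 0.76. On chromosome 29 the region at 51301146 was at 0.28 ± 0.26 and 1.21 ± 0.72, and that at 50373046 at 0.31 ± 0.66 and 1.11 ± 0.47 (SD, n = 4 each). Their unadjusted limma p between the groups were 0.0170, 0.0153, 0.0155 and 0.0387. In the same order, low-gain heifer 5 lay at -0.61, 0.16, 0.18 and 0.46, each time inside the high-gain range. Low-gain heifers 6, 7 and 8 lay at -2.72 to -2.14, 1.22 to 1.85, 1.23 to 1.80 and 1.06 to 1.54. These group differences thus came from heifers 6, 7 and 8 rather than from all low-gain heifers. The enriched channel alone holds no input and so measures probe brightness. There each of the 5 lowest regions lay above the array median (0.28 to 2.73). Without the brightest input probes, the means on chromosome 7 and on chromosome 29 at 50600406 were -0.46 and -0.34 and did not pass (limma, adjusted p = 0.115 and 0.232), nor did that at 50373046 (0.64, 0.0797). With normexp the 5 highest means were 0.27, 0.28, 0.20, 0.24 and 0.34, and the calls at 51301146, at 50373046 and on chromosome 11 were lost (limma, adjusted p = 0.0599, 0.160 and 0.0726). Loess gave 0.44 on chromosome 11. Within slide row 1 the calls on chromosomes 19 and 11 and at 51301146 and 50373046 were lost (0.49, 0.47, 0.41 and 0.54), and within slide row 2 that at 50373046 (0.88), while the region on chromosome 5 was at 0.98 and passed within slide row 1 and at 0.39 within slide row 2. With the enriched channel alone the first 4 of the highest were at 2.03, 2.51, 3.27 and 2.67, and that on chromosome 5 at 0.080. The call at 50373046 was also lost without low-gain heifer 6, 7 or 8 (0.67, 0.64 and 0.72), and that at 51301146 without low-gain heifer 8 (0.68). The region on chromosome 5 passed without low-gain heifer 7 (0.99). The 124 regions became 259 without low-gain heifer 5, 77, 50 and 70 without high-gain heifers 1, 3 and 4, and 41, 63 and 40 without low-gain heifers 6, 7 and 8. Those 124 also became 286 with normexp, 253 with loess and 319 with array weights. They became 78 with scaling, 31 with the robust trended fit and 24 within slide row 1. The number below was 17 without high-gain heifer 2, 6 without high-gain heifer 4 and 20 without low-gain heifer 5.

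High-gain heifers were higher at 44.7% of probes (exact permutation p = 0.200, two-sided), a share that centring each array holds near equality and that says nothing about the overall level. The interquartile range of the log2 ratio was 1.32 ± 0.62 (SD, n = 4) in high-gain and 1.88 ± 0.51 (SD, n = 4) in low-gain heifers (exact permutation p = 0.257, two-sided), a difference of -0.79 within slide row 1 and -0.33 within slide row 2. The enriched channel was well above background at 73.8% ± 2.26 of probes in high-gain and 62.3% ± 8.58 in low-gain heifers (SD, n = 4 each), with no overlap between the groups. That had a two-sided exact permutation p of 0.0286, the smallest this design allows, and 0.286 after Benjamini-Hochberg adjustment over 10 measures. The difference was 9.22 percentage points within slide row 1 and 13.8 within slide row 2.

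Heifers of 1 group did not share a ratio profile to the same degree. Across probes, which are not independent replicates, low-gain heifers 6, 7 and 8 correlated in pairs at r = 0.574 to 0.668. Low-gain heifer 5 correlated with those 3 at 0.0911 to 0.141, and with the high-gain heifers at 0.135 to 0.211. The high-gain heifers correlated with one another at 0.0401 to 0.187. High-gain heifer 3 correlated with low-gain heifers 6, 7 and 8 at 0.277 to 0.305 and high-gain heifer 4 at 0.167 to 0.217, above their values with each other high-gain heifer. Input channels correlated at 0.765 to 0.915 over all pairs. Over the 4495 probes well above background in both channels on all arrays, low-gain heifer 5 still correlated with heifers 6, 7 and 8 at no more than 0.115.

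**Figure D2:**
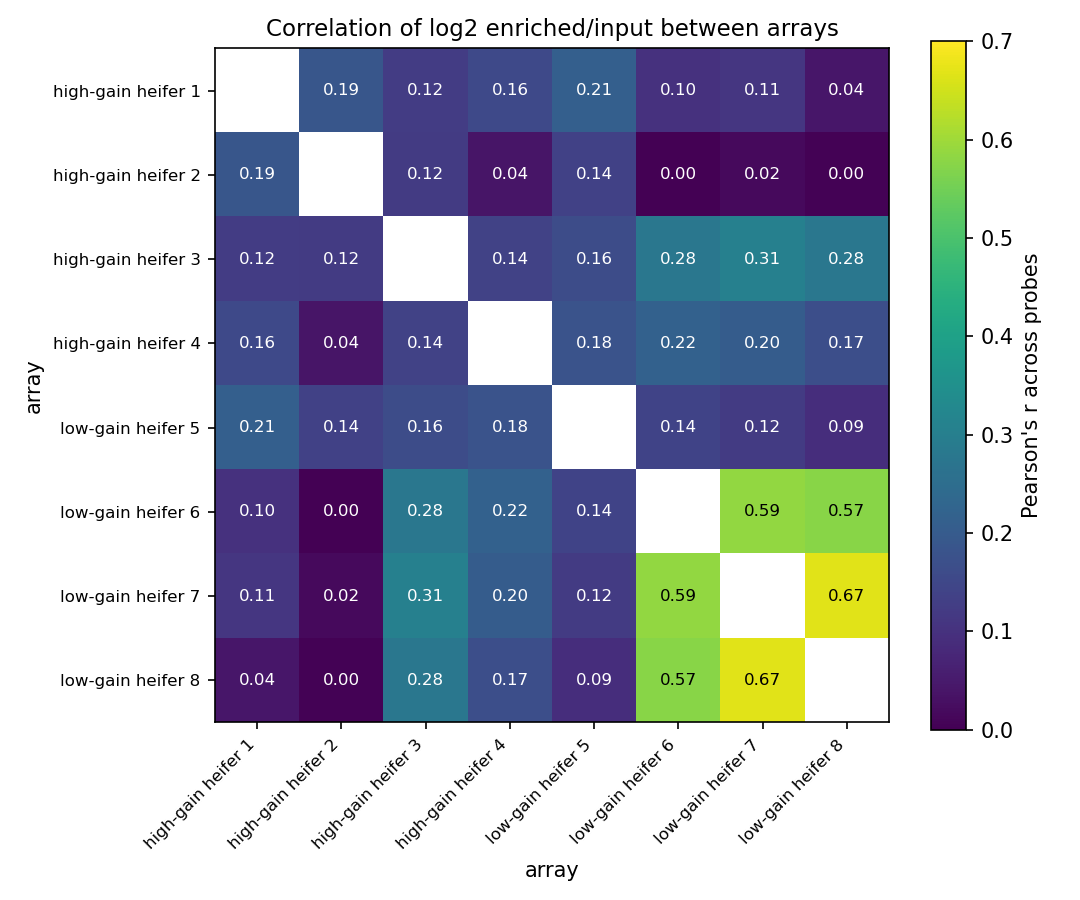
Pearson's r of the log2 enriched-to-input ratio across 10249 probes for each pair of the 8 arrays (both axes), with colour and printed value giving r. Low-gain heifers 6, 7 and 8 reach 0.668 with one another, and low-gain heifer 5 reaches 0.141 with them.

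Of the 35 ways to split the 8 arrays into 4 and 4, the feeding groups gave the third largest number of probes at unadjusted p under 0.05 (limma).

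**Figure D3:**
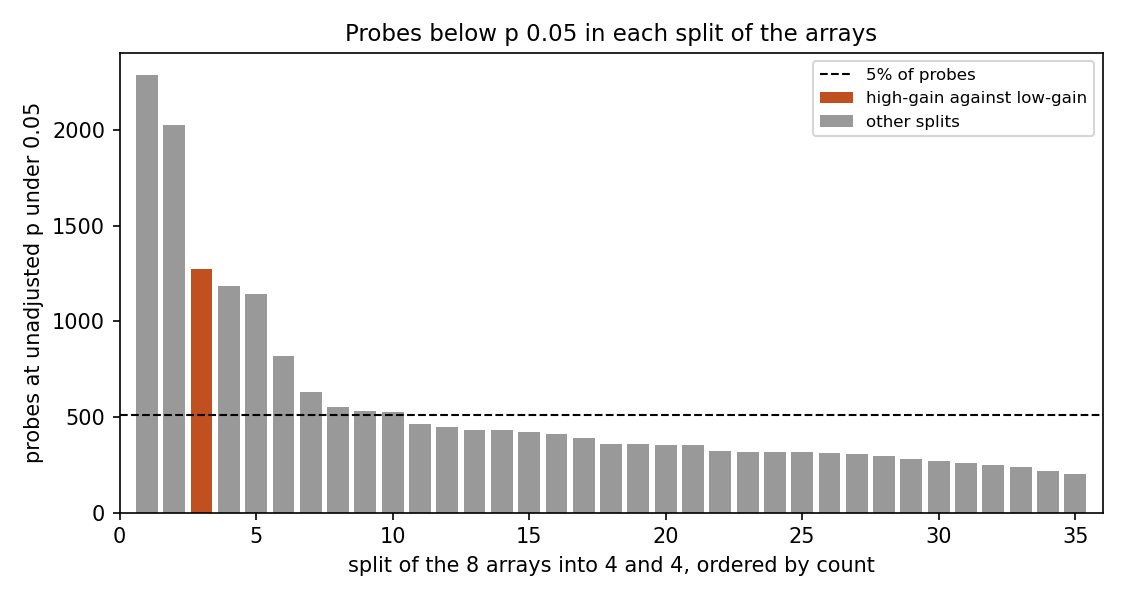
Number of probes at unadjusted p under 0.05 (y axis, limma) in each of the 35 splits of the 8 arrays into 4 and 4 (x axis, ordered by count), with 5% of the probes as a dashed line. The feeding groups gave 1275 probes, and the highest other split gave 2287.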

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

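Tests of single explanations here were chosen after the result was seen, except those of bright input probes for heifer 5, and of probe span, input brightness and splits for the lean of chromosome 29. For these the prediction was written before the test, though leaving out the brightest input probes was itself an addition made after seeing the data.

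A single array lay far from the others of its group in 3 of 70 groups of values examined, where chance gives about 1 in 20. The brightest enriched signals (99th percentile of intensity) were at 34133 in low-gain heifer 5 against 136757 to 140167 in the other low-gain heifers. In high-gain heifers they were at 44081 to 52705. At the run on chromosome 5 from 51895471 to 51896901, high-gain heifer 4 lay at 1.66 against 0.45 to 0.58 in the other high-gain heifers. At the run on chromosome 21 from 65897495 to 65898115, high-gain heifer 4 lay at 0.85 against 0.57 to 0.60.

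Low-gain heifer 5 stood apart from the other low-gain heifers. Dim probes and bright input probes as the only source are argued against by its highest correlation with another low-gain array. That was 0.115 among well-measured probes and 0.134 without the brightest input probes. A weaker enriched signal over all probes stays open, since leaving out dim probes cannot detect it. The 99th percentile of its enriched signal (34133) was the lowest of the 8 arrays. With the low-gain arrays of its slide row or column its correlation was at most 0.141. This restates the low correlations and cannot judge its place on the slide, which no other array held. A failed input is argued against by its input correlation of up to 0.914. An exchange with a high-gain heifer is not settled. The highest correlation between a high-gain array and low-gain heifers 6, 7 and 8 was 0.305. That cannot decide it, since high-gain heifers correlated with one another at only 0.0401 to 0.187, so arrays of 1 group need not correlate. Unequal recovery of methylated DNA may account for it, since its enriched signal followed its own input at r = 0.905, against at most 0.852 in the other low-gain heifers. In high-gain heifers 1 to 4 that correlation was 0.941, 0.932, 0.878 and 0.797. Heifer 5 thus lay inside the high-gain range, so the value cannot tell unequal recovery from a wrong label. A single wrong label also stays open, since at 300 probes chosen without it heifer 5 lay at 0.133 on a scale from the mean of the other group (0) to that of its own (1), but high-gain heifers 3 and 4, each treated alike, lay at 0.499 and 0.368, no nearer their own group than the other. A difference between animals in their response to the diet stays open as well, as untested. Which arrays are the unusual ones is not settled either. The factor that scaled the enriched channel in dye normalisation was 20.3, 22.3 and 36.2 in low-gain heifers 6, 7 and 8. It was 17.3 in heifer 5 and 11.1 to 17.0 in high-gain heifers. A technical trait shared by low-gain heifers 6, 7 and 8 was not tested.

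For the chromosome 29 region at 50882389 to 50883681, a difference in input DNA is argued against, since the input differed by -0.27 and the enriched channel by 1.84. Its bright input probe as the only source is argued against, since the other probe well above background in both groups differed by 2.54 (standard error 0.57). Of the 35 splits, 6 gave at least 1 region past the threshold, the highest other giving 85, so chance could account for a count of 1. An effect of the feeding schedule on this region remains a hypothesis.

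Regions of chromosome 29 leaned towards lower values in high-gain heifers, by a mean of -0.19 (standard error 0.035 over regions, which share the same 8 arrays and are not independent) relative to other chromosomes, but with normexp background correction 25 were higher and 11 lower at unadjusted p under 0.05, in place of 9 and 35. Probe span, a stand-in for base composition since shorter probes tend to be richer in G and C, may account for it, since matching regions on span left -0.035. Matching on input brightness left -0.15, which decides neither way. Chance is not excluded, since 2 of the 35 splits gave as large a difference between the directions, 26 for the feeding groups and 63 for the highest other. An effect of the schedule stays open.

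Chance was also not excluded for the other counts. Of the 35 splits, 3 gave as many probes at unadjusted p under 0.05 (1275, highest other 2287), 3 as many regions at unadjusted p under 0.05 (139, highest other 290), 3 as many runs (13, highest other 38) and 4 as large a largest run (12.7, highest other 21.4). For the 0 probes and 0 loci past the adjusted threshold (limma; 1275 and 14 at unadjusted p under 0.05) the splits test nothing, since all 35 give at least 0, and the highest others gave 214 probes and 41 loci. The split that exchanged low-gain heifer 5 with high-gain heifer 4 gave those 214 probes, 85 regions and 41 loci, and the one that exchanged it with high-gain heifer 3 gave 211 probes and 8 regions. Such counts point to a structure of the samples, and restate that heifer 5 was unlike the other low-gain heifers rather than adding evidence for it.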

How the results depend on the processing

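Normexp on medians, the authors' values without centring, slide column, single slide rows, the brightest input probes and the tiled loci were chosen after seeing the data. Planned normexp on mean signals, the test per gene and all gene lists were not run, and the spread of ratios was not taken under settings that equalise it. No paired analysis was possible because the groups share no replicate number. Dim enriched signal limits many probes, and the cause of the shifts below was not tested except where fewer probes or heifers show it. The chromosome 29 region kept its sign in 24 of 24 alternatives and its call in 9, with limma adjusted p from 0.000203 to 0.331. Results of the named runs under alternatives kept sign and side of unadjusted p 0.05 in 283 cases, kept only the sign in 24, most often within slide row 1, and turned sign in 2. The runs were picked in these same arrays by p under 0.05 at each probe. Keeping that side is therefore in part built in and is no separate support.

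Leaving out 1 heifer at a time gave 0 to 308 probes, 0 to 25 regions, 0 to 10 loci, 6 to 30 runs and 6 to 20 regions below the median, each highest count without low-gain heifer 5. Without high-gain heifer 4, 2 loci passed and 6 regions lay below, and without high-gain heifer 2, 17 lay below. Runs numbered 6 without high-gain heifer 2, low-gain heifer 6 or low-gain heifer 7, 7 without low-gain heifer 8 and 8 without high-gain heifer 1. The interquartile range differed by -0.84 to -0.38 and the share of probes was 43.1% to 46.5%. Array weights gave 332 probes, 192 regions, 32 loci and 105 runs. Normexp gave 2 probes, 7 regions, 3 loci and 4 regions below, and turned the lean of chromosome 29 (25 regions higher, 11 lower at unadjusted p under 0.05), while the authors' values centred gave 10 and 32. The authors' values gave 1 probe and 6 regions below when centred. Not centred, the same amount is added at every probe, 0.77 to the group difference and -0.89 to the profile mean, so what follows for these values says nothing about single items. They gave 1 probe, 30 regions, 42 loci, 52 runs, 407 regions below and a share of probes higher in high-gain of 85.1%. The chromosome 16 run then turned to 0.021, and the 5 highest profile regions to -0.17 (chromosome 11), -0.18 (chromosome 19), -0.16 and -0.17 (chromosome 29) and -0.23 (chromosome 5).

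The enriched channel alone holds no input, so its levels and spread describe probe brightness and not enrichment over input. It gave 0 regions, 1 locus, 1 run, 168 regions above and 63 below. Its interquartile range differed by 0.46, a quantity unlike the -0.56 of the ratio. The chromosome 17 run differed by 0.11 in that channel. The lowest profile regions were at 2.73 (chromosome 7), 1.24 (chromosome 29), 0.56 (chromosome 20), 1.85 (chromosome 8) and 0.28 (chromosome 6) there. Loess gave 0 regions, 6 runs and 6 regions below, and quantile normalisation 2 regions. Probes well above background in input gave 0 regions, 19 below and a share of 51.3%, and those in both channels 0 regions, 3 loci, 5 runs and 1 region above. The slide column as a block gave 0 regions. Slide row 1 alone gave 0 regions, 4 runs and 6 regions below, and row 2 alone 0 regions, 2 above and 31 below. Without the brightest input probes there were 0 regions and 6 runs. Gaps of 500 bp gave 0 regions and 31 below, and gaps of 2000 bp 0 and 1. Runs of at least 2 probes numbered 102, of at least 4 probes 3, and at p under 0.01 for each probe 2. Counts of 0 for regions are limma's, with 74 to 156 regions at unadjusted p under 0.05 under these settings and 76 to 182 with a heifer left out.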

Other observations

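These measures of each array were chosen after the results were seen. At the 103 probes in the top 1% of mean input, the mean log2 ratio was 0.72, 1.20 and 0.52 in low-gain heifers 6, 7 and 8 and -0.67 in low-gain heifer 5. In high-gain heifers 1 to 4 it was -0.082, 0.30, -0.30 and 0.19.

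The rank correlation of the log2 ratio with probe span, across probes, was -0.0524, 0.219, -0.0176 and -0.277 in high-gain heifers 1 to 4. In low-gain heifers 5 to 8 it was -0.0211, -0.305, -0.319 and -0.254. Neighbouring probes with starts at most 200 bp apart correlated within an array at 0.101 in low-gain heifer 5 and at 0.313 in low-gain heifer 8, the lowest and highest of the 8.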
